A study of Mus musculus with 6 samples.

How the data were processed

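RNA-seq was carried out on cells labelled as liver lymphatic endothelial cells and sorted from mice that carry a green fluorescent reporter of the interleukin 7 gene (Il7). Per the labels' protocols, 20000 to 50000 cells per sample went straight into TRIzol, total RNA was extracted and libraries were made after depletion of ribosomal RNA. There were 6 libraries, 3 from sham-operated mice and 3 from mice at day 3 after ischemia and reperfusion (I/R), an injury in which blood flow is interrupted and then restored. Column names in the deposited table carry the words "GFP plus". The gating markers, the animals behind each sample, the sham time point, the read layout and the gene annotation are not given in the sources used here. Since no label ties a sample to a separate animal, p-values measure only the spread between these samples.

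The deposited values are a signal of normalised counts, scaled by the authors to 1 factor per library. The submitters' processing notes name Trim Galore 0.5.0, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 1.22.1 with the mouse build mm10, without stating the role of each. The table held 22027 genes, every one typed as protein coding, so other RNA classes were not analysed here. Of the gene identifiers, 21886 were found in GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, when version numbers were ignored, and 18937 with their version. Coordinates come from that release. A total of 30 gene symbols were shared by several identifiers, among them Ccl21a, for which 1 of the identifiers was at 0 in all 6 libraries. Reads of near-identical copies such as the Ccl21 genes, Saa1 with Saa2, and the guanylate-binding proteins could be split between genes, so those values are uncertain.

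Dividing each column by its smallest value above 0 gave whole numbers for 100% of values, within a tolerance of 0.01, and median-of-ratios factors recomputed from these recovered counts equalled the deposited ones (ratio 1). The recovered counts sum to 6638130, 15650152 and 8616652 for sham libraries 1, 2 and 3, and to 6297308, 17086746 and 13323676 for I/R libraries 1, 2 and 3. Since StringTie is named and no source states how genes were counted, the recovered counts may be derived from coverage and not be read counts. Floors, binomial intervals and the count models treat them as read counts. A floor of 3 counts corresponds to deposited values of 4.89, 2.0 and 3.58 in the sham libraries and 4.56, 1.83 and 2.34 in the I/R libraries, and floors and binomial intervals cover counting error only. Chi-square per degree of freedom between pairs of libraries was 26.2 to 57.9, so no pair agreed within sampling noise and each library counted once.

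The comparison of I/R day 3 with sham was fitted in R 4.3.3 with limma 3.58.1 on log2(value + 1), with an intensity trend and no covariate. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean value of at least 10 over the 6 libraries were tested, which left 13434. Fold changes are differences of mean log2(value + 1). The added 1 draws those of low genes towards 0, yet where libraries of a group differ widely they can exceed the count model's, as for Il7 (1.66 in limma, 1.43 in DESeq2). An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Because the values were normalised and not raw counts, limma was the test, and edgeR 4.0.16 on the same genes and DESeq2 1.42.0 with its own filter, which left 16662 genes, were run on the recovered counts as alternatives. Among the tested genes, 14 had no DESeq2 adjusted p and were left without one.

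Before the data were examined, 32 gene lists were fixed for liver endothelium, for the other cells a liver sort could hold and for injury responses. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 31 lists, with camera at an estimated correlation and fry beside it. The mesothelial list had 4 tested members and was not tested. Where a symbol had several identifiers, the one with the highest mean entered its list, a choice made after a first run had counted such symbols more than once. Another 4 lists were written after the data were seen, for recruited monocytes, lipid-associated macrophages, resident Kupffer cells and sterol synthesis.

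The genes named in the text follow a rule that was also fixed in advance. It takes 10 genes per direction by size of change among those past the threshold with a mean of at least 50 and no overlap between the groups. Where fewer passed, the smallest unadjusted p filled the number up, with the same mean and separation asked of the fillers, and these are named as not passing. It adds up to 4 members of each list with a call or with a called member, up to 2 of each other list, and 12 fixed genes. Outside the rule, Cd5l, Clec4f, C1qb, Cd3e and Cd79a were named after their values were seen, and so were those listed as such in the closing section. Alternatives covered the pseudocount, the filter on low values, scaling, the limma settings, the replicate number as a block, each library left out in turn, the tool, the threshold and the list test. Added after seeing the data were a fit without both shallowest libraries, DESeq2 adjusted over the genes with a mean of at least 10, and a fit with a covariate that sets the 2 libraries with the most detected genes (sham 2 and I/R 1) against the other 4.

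The scripts were tested on simulated data built from the 13434 tested genes with 200 genes changed. For the comparison of I/R day 3 with sham, limma recovered 25.4% of genes changed 2-fold, 69% changed 4-fold and 83.9% changed 8-fold, with 6 false calls among 124. The matching shares were 31.3%, 74.6% and 85.5% for edgeR, with 5 false calls among 132, and 40.3%, 76.1% and 85.5% for DESeq2, with 23 false calls among 157. With no gene changed, limma called 0 genes and 0 lists. Each gene was drawn independently, at the spread that edgeR's trend gave for its level. The simulated data therefore hold no correlation between genes and no outlying library, and the 0 list calls do not test the preset correlation of 0.01.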

Results

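Lymphatic endothelial cells line the vessels that drain tissue fluid and immune cells from the liver. Libraries labelled as such cells, sorted from Il7 reporter mice, were compared between 3 sham libraries and 3 libraries from day 3 after I/R, to find which transcripts differ after the injury. Library depth ranged from 6297308 to 17086746 recovered counts, and 18835 of 22027 genes had a value above 0 in at least 1 library.

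Macrophage transcripts were among the most abundant in all 6 libraries, alongside clear expression of lymphatic genes. Cd5l and Clec4f, markers of Kupffer cells, the resident macrophages of the liver, ranked 5 and 6 by mean value, and Csf1r and the complement gene C1qb ranked 20 and 22. Alb, which encodes the hepatocyte protein albumin, ranked 15. The lymphatic transcription factor gene Prox1 ranked 1459 and Pdpn, encoding podoplanin, ranked 5056, while the mean of Clec4f was 33.6 times that of Prox1, with 15.1 to 58.8 times in single libraries. Other lymphatic genes lay higher, with Mmrn1 at rank 94, the chemokine gene Ccl21a at rank 205 and the receptor gene Flt4 at rank 488. Il7 ranked 10547. The T cell gene Cd3e had 0 counts in all 6 libraries, and the B cell gene Cd79a had 12 counts over all 6.

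**Figure D1:**
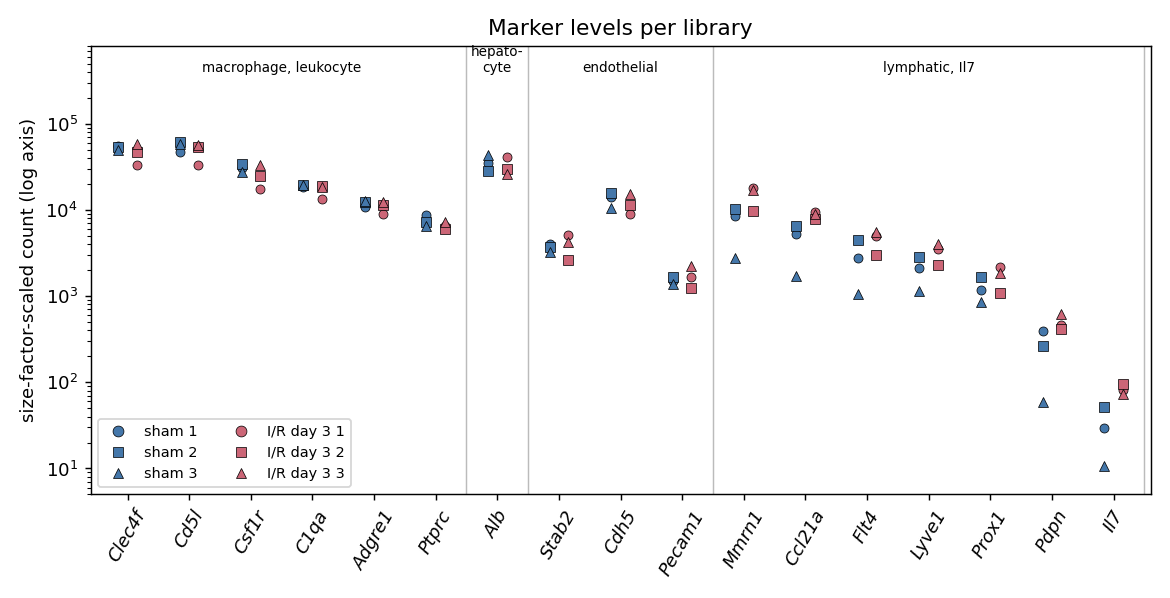
Size-factor-scaled counts of marker genes on a log axis, with each point 1 library, blue for sham and red for I/R day 3. Clec4f lay between 32860 and 58480 and Prox1 between 849.6 and 2177, and sham library 3 had the lowest Flt4 (1066) and Ccl21a (1726).

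Levels of these cell type markers overlapped between the groups for most genes. Clec4f was at 52830 ± 2520 (SD, n = 3) in sham and 46080 ± 12800 (SD, n = 3) in I/R libraries, and Alb at 35650 ± 7440 and 32250 ± 7610. Ptprc, the gene for the pan-leukocyte protein CD45, had a log2 fold change of -0.18 (SE 0.18, limma adjusted p = 0.985), or -0.062 without sham library 1 and -0.27 without sham library 3. Pecam1, a general endothelial gene, had 0.14 (SE 0.22, adjusted p = 0.986) and Stab2, a sinusoidal endothelial gene, 0.08 (SE 0.24, adjusted p = 0.995). The proliferation gene Mki67 had -0.23 (SE 0.28, adjusted p = 0.985) and Alb -0.15 (SE 0.25, adjusted p = 0.987). The signs of these last 4 and of Vegfc turned when single libraries were left out.

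At day 3 after I/R, 4 genes rose and 0 fell past the threshold. Adam8, a membrane metalloprotease gene expressed by leukocytes, went from 47.9 ± 6.68 in sham to 520.4 ± 245 in I/R libraries (SD, n = 3 each), a log2 fold change of 3.33 (SE 0.35, limma adjusted p = 0.0249). Gpnmb, a transmembrane glycoprotein gene of macrophages, went from 223.1 ± 123 to 1910 ± 937, a log2 fold change of 3.12 (SE 0.40, adjusted p = 0.0416). F13a1, which encodes the A subunit of coagulation factor XIII, went from 403.0 ± 151 to 1778 ± 399, a log2 fold change of 2.18 (SE 0.28, adjusted p = 0.0416). Gda, encoding guanine deaminase, went from 212.1 ± 8.24 to 745.8 ± 150.4, a log2 fold change of 1.79 (SE 0.22, adjusted p = 0.0416). Each of the 4 was higher in every I/R library than in every sham library. The data do not show which cells in the libraries carried these 4 differences.

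In GRCm38 the gene body of Adam8 (ENSMUSG00000025473) spans 139978932 to 139992562 on the minus strand of chromosome 7, and that of Gpnmb (ENSMUSG00000029816) 49036546 to 49070929 on the plus strand of chromosome 6. F13a1 (ENSMUSG00000039109) lies on the minus strand of chromosome 13 from 36867178 to 37050244, and Gda (ENSMUSG00000058624) on the minus strand of chromosome 19 from 21391307 to 21473445.

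At an unadjusted p under 0.05 limma found 596 genes, 397 higher and 199 lower, and the split was 490 and 130 with equal totals and 370 and 240 with quantile normalisation. It was 207 higher and 216 lower without I/R library 1, and 695 and 378 without sham library 1. The groups did not overlap for 1288 of 13434 genes, or 9.6%, where chance gives 10% for 3 against 3. On the recovered counts edgeR called 1 gene higher, Adam8, and 0 lower, and DESeq2 called 35 higher and 7 lower among 16662 genes, with all 4 limma genes among them. Adjusted over the genes that limma tested, DESeq2 called 37 higher and 7 lower. Without sham library 1 limma called 20 genes higher and 2 lower, and without any 1 of the other 5 libraries it called 0. The 4 calls also ended in limma without the trend, with adjusted p of 0.866 to 0.97.

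The genes next in rank did not pass the limma threshold. On the higher side they included Ccr2 and Ccr1, chemokine receptor genes of monocytes, with log2 fold changes of 2.29 (SE 0.35) and 2.09 (SE 0.33) and an adjusted p of 0.115 for both. Thbs1, encoding the matrix glycoprotein thrombospondin 1, had 1.52 (SE 0.24, adjusted p = 0.115) and Cd93, a gene of endothelial and myeloid cells, 1.62 (SE 0.24, adjusted p = 0.1). The acute phase gene Saa2 had 2.01 (SE 0.34) and the metalloprotease gene Adam15 1.26 (SE 0.21), each with an adjusted p of 0.16. On the lower side were Tlr7, a sensor of single-stranded RNA, at -1.04 (SE 0.20, adjusted p = 0.329), and Helz2 at -0.77 (SE 0.18, adjusted p = 0.571). The interferon-induced genes Cxcl10, Cxcl9, Gbp4 and Gbp5 had -0.64, -0.93, -0.84 and -0.57, and Trim26, Pira2, Mvd and Hcar2 had -0.74, -1.25, -1.10 and -0.66, with adjusted p of 0.634 to 0.825 over these 8.

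**Figure D2:**
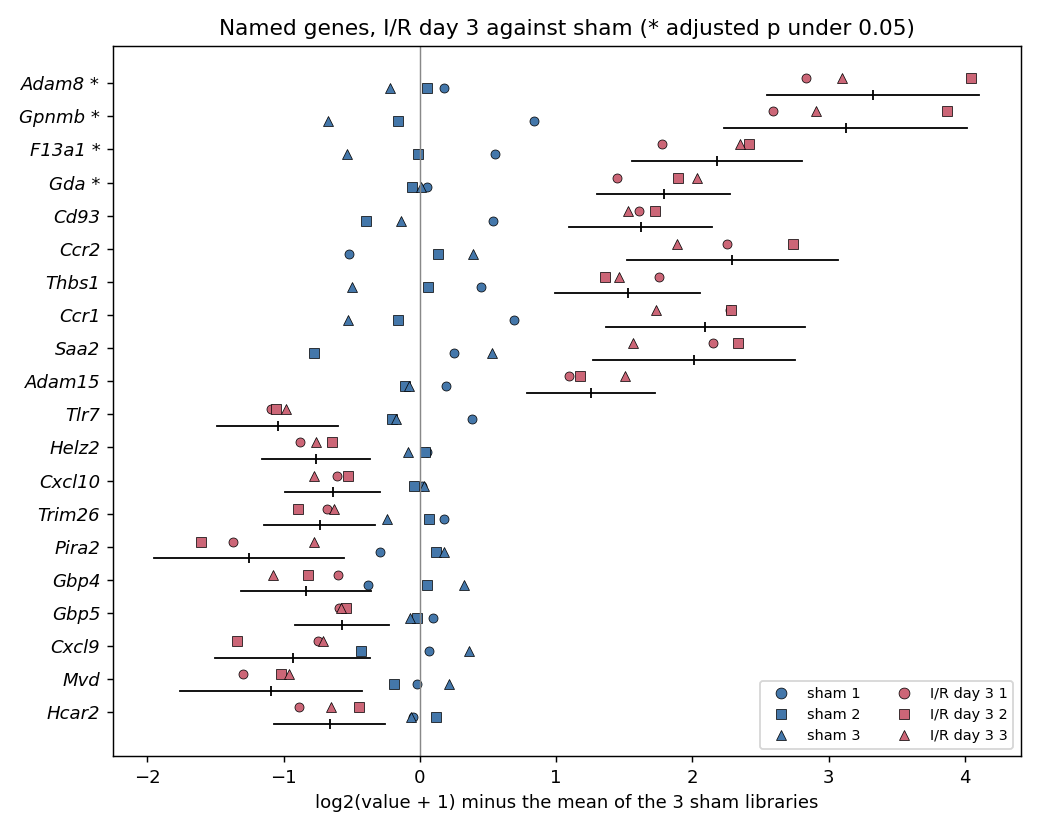
Log2(value + 1) of the 10 genes per direction that the naming rule took, as the difference from the sham mean. Genes short of the threshold were filled in by smallest unadjusted p and not by size of change. Each point is 1 library and the black line is the 95% interval of the limma log2 fold change. Asterisks mark Adam8, Gpnmb, F13a1 and Gda, the 4 genes past the threshold.

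Among the gene lists, 13 of 31 stood apart from the other genes at the preset correlation, 9 higher and 4 lower, and with quantile normalisation the split was 13 higher and 3 lower. With an estimated correlation 0 of the 13 calls held, at limma camera adjusted p of 0.0747 to 0.474. Every call by camera therefore rests on the preset correlation. In fry's directional test the interferon list passed (adjusted p = 0.0311) and the other 12 did not. Lists share members, so their calls partly count the same genes. Tested members also found in another list were 7 of 23 for lymphatic identity, 5 of 20 for pan-endothelial and 8 of 23 for lymphangiogenic. They were 6 of 16 for the blood vascular list and 9 of 24 for the NF-kappaB and TNF list.

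Lymphatic and endothelial gene lists stood higher than the other genes at the preset correlation, while their means overlapped between the groups. Of 23 tested lymphatic identity genes, 21 had a positive fold change with a median of 0.75, 0 passed alone, and the list had a camera adjusted p of 1.7e-08 (0.454 with an estimated correlation). Its mean log2 value was 9.99 in I/R library 2 against 10.28 in sham library 2 (exact permutation p = 0.2 between the groups). Il7 went from 30.4 ± 20.3 to 83.2 ± 10.7 (SD, n = 3 each), a log2 fold change of 1.66 (SE 0.59, 95% interval 0.35 to 2.97, limma adjusted p = 0.985). Ccl21a, whose product guides leukocytes into lymphatics, had 1.17 (SE 0.40), Pdpn 1.43 (SE 0.56), Mmrn1 1.20 (SE 0.44), and the scavenger receptor gene Stab1 0.75 (SE 0.21). Flt4, the gene for VEGF receptor 3, had 0.87 (SE 0.44), Lyve1 0.73 (SE 0.32) and Prox1 0.47 (SE 0.30), and adjusted p for these 7 genes was 0.862 to 0.985. Vegfc, encoding a ligand of that receptor, was listed at 0 in sham library 3 and at 3.89 to 29.3 in the others. Sham library 3 had the lowest values of Il7, Prox1, Pdpn, Lyve1, Flt4, Ccl21a and Mmrn1. Without it the list median was 0.30, and log2 fold changes were 1.07 for Il7, 0.58 for Ccl21a, 0.615 for Pdpn, 0.62 for Mmrn1, 0.29 for Flt4, 0.37 for Lyve1 and 0.22 for Prox1.

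The pan-endothelial list had 17 of 20 positive members with a median of 0.40 (camera adjusted p = 1.65e-05, and 0.474 with an estimated correlation), among them Cldn5 at 0.94 and Tek at 0.61. The lymphangiogenic list had 19 of 23 positive members with a median of 0.41 (adjusted p = 0.00078, and 0.454 with an estimated correlation), including Nrp2 at 0.99 and Angpt2 at 1.24. The blood vascular list had 11 of 16 positive members with a median of 0.27 (adjusted p = 0.0186, and 0.454 with an estimated correlation), including Hey1 at 1.09 and Vwf at 1.08. Of these 3 lists 0 members passed over all genes or when adjusted over the list alone. In I/R library 2 the list means were 9.03, 8.55 and 7.0 on the log2 scale, each below sham libraries 1 and 2 (exact permutation p = 0.3 for each list). Without sham library 3 the limma camera adjusted p was 0.0636 for the lymphangiogenic list and 0.0558 for the blood vascular list. For the latter it was 0.275 without I/R library 3, 0.0653 with no filter, 0.116 without the trend and 0.0652 without both shallowest libraries. Without I/R library 1 the medians were 0.28, 0.24 and 0.076, and without I/R library 3 that of the blood vascular list was 0.10 and that of the pan-endothelial list 0.27. Without I/R library 2 these 2 medians were 0.50 and 0.70. Log2 fold changes without sham library 3 were 0.56 for Cldn5, 0.54 for Nrp2 and 0.67 for Angpt2, and that of Vwf was 0.58 without I/R library 3.

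The matrix, coagulation and acute phase lists also stood higher than the other genes at the preset correlation. The basement membrane and extracellular matrix list had 24 of 30 positive members with a median of 0.56 (camera adjusted p = 1.98e-05, and 0.474 with an estimated correlation), and Fn1, the fibronectin gene, at 0.93 (SE 0.21) passed when adjusted over the list alone. The coagulation and fibrinolysis list had 13 of 18 positive members with a median of 0.49 (adjusted p = 0.000207, and 0.454 with an estimated correlation), and 3 passed when adjusted over the list alone, namely Thbs1, Anxa2 at 0.79 and Pros1 at 0.69. The acute phase list had 13 of 17 positive members with a median of 0.27 (adjusted p = 5.51e-05, and 0.454 with an estimated correlation), with Saa2 and Saa1 at 2.01 and 1.63 passing when adjusted over the list alone. Over all genes 0 members of these 3 lists passed. Mean values of the groups overlapped for the matrix and coagulation lists (exact permutation p = 0.3 and 0.2) and not for the acute phase list (0.1). Without sham library 3 the limma camera adjusted p of the matrix list was 0.192 and its median 0.14, and without sham library 2 the adjusted p of the coagulation list was 0.0532. Medians were 0.74 for the coagulation list without sham library 1 and 0.45 for the acute phase list without I/R library 3.

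The neutrophil and monocyte list, with 8 of its 15 members tested, had 5 positive members and a median of 0.48 (camera adjusted p = 0.0232, and 0.454 with an estimated correlation). Ccr2 passed when adjusted over the list alone, Ltf and Mmp9 had 1.75 and 0.94, and the cytokine gene Il1b had -0.19. In fry's test for change in either direction its adjusted p was 0.00325. All 12 tested mitochondrially encoded genes had positive fold changes with a median of 0.34 (adjusted p = 0.00191, and 0.474 with an estimated correlation). Among them mt-Nd4 stood at 2899 in sham library 1 and between 10550 and 20170 in the other libraries. Mean values of the groups did not overlap for the neutrophil and monocyte list or the mitochondrial list (exact permutation p = 0.1 for both). Without sham library 2 the limma camera adjusted p was 0.167 for the neutrophil and monocyte list and 0.246 for the mitochondrial one, whose median was then 0.12. For the neutrophil and monocyte list it was 0.173 with no filter and 0.0703 without the trend, and the median was 0.27 without I/R library 1. Ltf had 1.11 without sham library 3, and Il1b -0.073 without sham library 1 and -0.31 without sham library 2.

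The interferon response and antigen presentation lists stood lower than the other genes, with each list's mean below all sham libraries in every I/R library (exact permutation p = 0.1 for both). Of 33 interferon response genes 29 had a negative fold change with a median of -0.32 (camera adjusted p = 4.48e-08, and 0.0747 with an estimated correlation). Gbp4 went from 6536 ± 1555 to 3623 ± 588 (SD, n = 3 each), and Stat2, a signal transducer of interferon receptors, had -0.55 (SE 0.18). Of 23 antigen presentation genes 21 had a negative fold change with a median of -0.27 (adjusted p = 2.33e-07, and 0.454 with an estimated correlation). The MHC class II genes H2-Eb1, H2-Ab1 and H2-Aa had -0.68, -0.61 and -0.50, and Cd74, the invariant chain gene, went from 58330 ± 7370 to 37030 ± 2460 (log2 fold change -0.65, SE 0.21). These genes were below every sham library in every I/R library, and their limma adjusted p was 0.706 to 0.985. Without sham library 1 the list medians were -0.19 for interferon and -0.43 for antigen presentation. Cd74 ranked 7 by mean value, next to the Kupffer cell markers Cd5l and Clec4f at 5 and 6. A resident Kupffer cell list, added after the data were seen, also had a negative median of -0.24 (camera p = 0.00269, and 0.378 with an estimated correlation). Which cells carried the lower values was not tested.

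The NF-kappaB and TNF list had 18 of 24 negative members with a median of -0.18 (camera adjusted p = 0.000637, and 0.454 with an estimated correlation), with Cxcl10 passing when adjusted over the list alone and Traf1 at 0.99. The endoplasmic reticulum stress list had 17 of 20 negative members with a median of -0.22 (adjusted p = 0.000475, and 0.454 with an estimated correlation), including Hyou1 at -0.54 and Creld2 at -0.52. Over all genes 0 members of these 4 lower lists passed. Mean values of the groups overlapped for the NF-kappaB and endoplasmic reticulum stress lists (exact permutation p = 0.2 for both). The limma camera adjusted p of the NF-kappaB and TNF list was 0.101 without sham library 1, where its median was -0.10, 0.151 with quantile normalisation and 0.226 without both shallowest libraries. Traf1 had 0.55 without sham library 2.

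**Figure D3:**
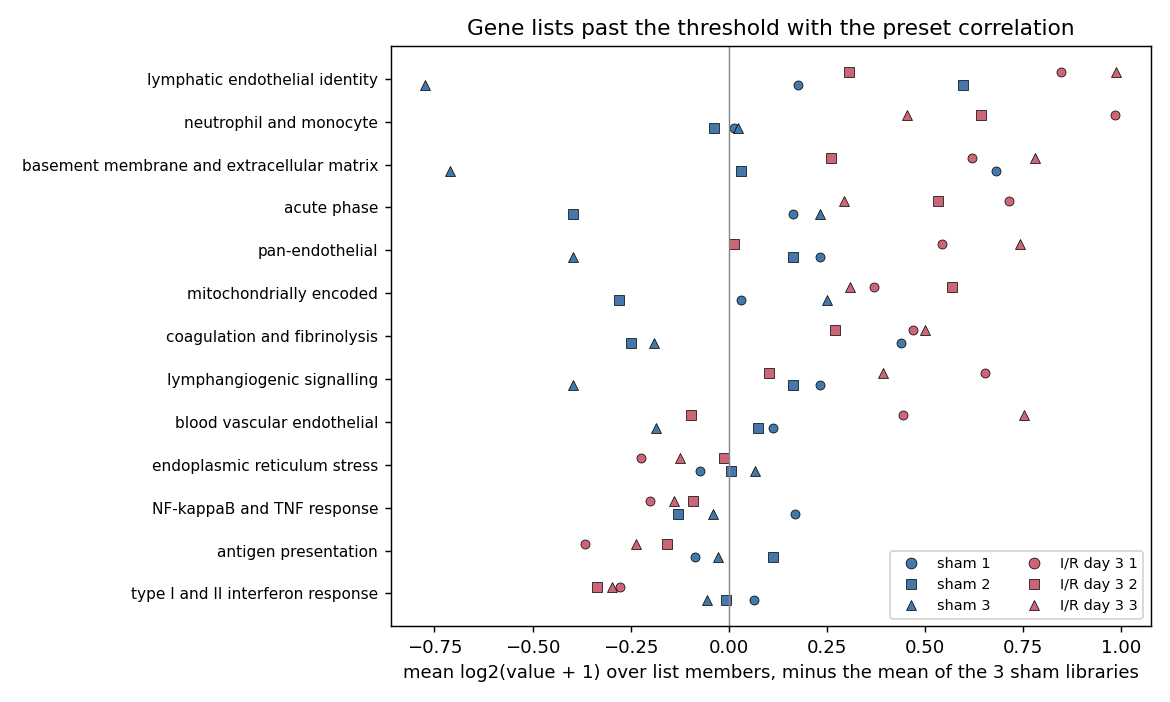
Mean log2(value + 1) over the members of each of the 13 lists with a call, as the difference from the sham mean, with each point 1 library. The 3 I/R libraries lay below all 3 sham libraries for the interferon and antigen presentation lists. They lay above all 3 sham libraries for the acute phase, neutrophil and monocyte, and mitochondrially encoded lists. Sham library 3 lay apart from the other sham libraries for the lymphatic identity list.

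No other cell type list that was tested had a call. The macrophage and Kupffer cell list had 5 of 16 positive members, with a median of -0.14 against a mean of 0.21 (limma camera adjusted p = 0.833). Without I/R library 1 the median was 0.016 and the list passed as higher (adjusted p = 0.0259), and without I/R library 3 the median was -0.25. Its Gpnmb passed over all genes, and Trem2 at 1.19 and Lyz2 at 0.85 also passed when adjusted over the list alone, while Csf1r had -0.32, or -0.080 without I/R library 1 and -0.53 without I/R library 3. The hepatocyte list had an adjusted p of 0.867, with a median of 0.07 and a mean of -0.03, and its G6pc had -1.37. Its median was -0.18 without sham library 2, where it passed as lower (adjusted p = 0.000303), and 0.18 without sham library 1 or 3. The camera adjusted p was 0.171 for liver sinusoidal endothelial genes, where Fcgr2b at 1.23 passed when adjusted over the list alone, 0.617 for lymphocyte genes, where Il7r at 4.36 did so, and 0.939 for erythroid and platelet genes, where Pf4 at 1.75 did so. Il7r was listed at 0 in sham libraries 2 and 3. Only 6 of 18 lymphocyte members and 6 of 12 erythroid and platelet members were tested, so these 2 results say little. Stellate cell and fibroblast genes had 0.691 and cholangiocyte genes 0.271. The sinusoidal list passed as higher without sham library 3 (camera adjusted p = 0.00653) or I/R library 2 (0.000615), and the stellate list without sham library 1 (1.39e-05). The cholangiocyte list passed as lower without I/R library 1 (8.27e-05) and as higher without I/R library 3 (0.0151).

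The remaining process lists also had no call. The limma camera adjusted p was 0.089 for mesenchymal transition, with S100a4 at 2.05 and Fn1 passing when adjusted over the list alone, and 0.105 each for junctions and valves, fatty acid use, proliferation and immediate early genes. It was 0.171 for hypoxia and glycolysis, 0.416 for nuclear-encoded oxidative phosphorylation, and 0.833 each for leukocyte trafficking and for apoptosis. In the trafficking list Ccl8 at 1.20, Cxcl9 and Cxcl10 passed when adjusted over the list alone. The oxidative stress list had 0.867, with the cystine transporter gene Slc7a11 at 2.06 passing when adjusted over the list alone, and the growth and survival cytokine list, which holds Il7, had 0.939. With 1 library left out, the proliferation list passed as lower without sham library 1 (camera adjusted p = 0.0324) and as higher without sham library 2 (0.0397), sham library 3 (3.87e-06) or I/R library 1 (1.04e-05). Passing as higher were mesenchymal transition without sham library 1 (0.041) or I/R library 2 (0.00591), junctions and valves without sham library 2 (0.0426) or I/R library 2 (0.00344), and fatty acid use without I/R library 1 (0.00424). Without sham library 1 trafficking (0.00709) and oxidative stress (0.0324) also did so. Passing as lower were immediate early genes without sham library 1 (5.64e-05) or I/R library 3 (0.0155) and oxidative phosphorylation without sham library 2 (0.0109) or I/R library 2 (0.0138).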

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

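The fits without both shallowest libraries, with the 2 libraries of most detected genes against the other 4 as a covariate, and with DESeq2 adjusted over the genes with a mean of at least 10 were chosen after seeing the data. The 4 higher and 0 lower genes of limma were also found with pseudocounts of 0.5 and 10, recomputed size factors, equal totals and a log2 fold change of at least 1. Higher genes numbered 5 with no filter and with quantile normalisation, and 4 of these were the same genes each time. They numbered 1 with a mean of at least 50, 0 without the trend, 2 with robust eBayes and 7 with array weights. They numbered 1 in edgeR, 35 in DESeq2, 37 in DESeq2 adjusted over the genes that limma tested, 0 without both shallowest libraries and 0 with the covariate, and lower genes numbered 7 in DESeq2 both ways. Leaving out 1 library gave 0 to 20 higher genes and 0 to 2 lower genes, with the highest values without sham library 1. The cause was not tested. Adam8 kept its call in 13 of 22 alternatives (adjusted p 1.11e-14 to 0.866), Gpnmb and F13a1 in 10 each and Gda in 11, and the direction of all 4 stayed the same in these.

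Same-numbered libraries did not deviate together, with correlations of -0.02, -0.21 and -0.001, and no sham library correlated best with the I/R library of its own number, so nothing shows that the numbers pair the samples. With the replicate number as a block limma called 0 genes higher and 0 lower (Adam8 adjusted p = 0.0624), and the 13 lists kept their calls.

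Of the 9 higher and 4 lower lists, 0 and 0 held with an estimated correlation and 0 and 1 with fry. Under all other alternatives 6 of the 13 kept their call. Of the 18 lists with no call, 14 gained one under at least 1 alternative and 14 changed direction under at least 1. Adjusted p here are camera's unless fry is named, and in DESeq2 camera ran on its test statistics. Where direction changed, the adjusted p of the hepatocyte list was 0.362 with quantile normalisation, 0.549 with array weights, 0.937 with the block, 0.468 without both shallowest libraries, and in fry's test 0.993. That of the erythroid and platelet list was 0.905 with a pseudocount of 10, 0.687 with no filter, 0.621 with quantile normalisation, 0.914 with equal totals, 0.907 without trend, 0.999 with the covariate, and in fry's test 0.954. The cytokine list had 0.983 with a pseudocount of 10, 0.988 with a mean of at least 50, 0.879 with quantile normalisation, 0.775 with array weights, 0.971 in DESeq2, 0.347 without both shallowest libraries, 0.999 with the covariate, and in fry's test 0.954. The lymphocyte list had 0.989 with no filter, and in DESeq2 the stellate and trafficking lists had 0.621 and 0.807. The immediate early list had 0.868 with quantile normalisation, and nuclear-encoded oxidative phosphorylation 0.889 with array weights and 0.206 without both shallowest libraries.

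Over the 6 fits without 1 library, lists that changed direction had adjusted p of 0.000615 to 0.907 (sinusoidal), 0.000303 to 0.936 (hepatocyte), 0.0259 to 0.98 (macrophage), 0.272 to 0.935 (lymphocyte), 1.39e-05 to 0.886 (stellate) and 8.27e-05 to 0.497 (cholangiocyte). The ranges were 0.367 to 0.966 (erythroid), 3.87e-06 to 0.871 (proliferation), 0.00709 to 0.901 (trafficking), 0.312 to 0.78 (cytokine), 0.0324 to 0.847 (oxidative stress), 0.0109 to 0.886 (oxidative phosphorylation) and 0.352 to 0.973 (apoptosis). Log2 fold changes over these fits were -0.074 to 0.35 for Pecam1, -0.14 to 2.32 for Vegfc, -0.33 to 0.003 for Alb, -0.13 to 0.36 for Stab2 and -0.48 to 0.046 for Mki67. Alb had 0.008 with quantile normalisation and Stab2 -0.053 without both shallowest libraries. The cause of these turns was not tested. Depth limits low genes such as Vegfc, with 68 counts over 6 libraries.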

Other observations

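Some tests were chosen after the results they bear on were seen. These were the tests of lipid-associated macrophage genes, of leukocytes of every kind, of macrophage RNA and of the lymphatic share. Also chosen after the results were seen were the gene names in the next paragraph, C1qa, C1qb, C1qc, Adgre1 and Reln, and the 4 added lists. The recruited monocyte test named its outcome for camera in advance without saying which correlation to use.

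The 35 higher genes that DESeq2 called on the recovered counts included Chil3, Osm, Lgals1 and Ednrb, which limma did not call. Chil3, a chitinase-like gene of activated macrophages, had a log2 fold change of 3.35 (SE 0.71, DESeq2 adjusted p = 0.0025), the cytokine gene Osm 1.65 (SE 0.39, adjusted p = 0.0118) and Lgals1, the galectin-1 gene, 1.77 (SE 0.36, adjusted p = 0.00104). Ednrb, an endothelin receptor gene, had 1.81 (SE 0.41, adjusted p = 0.00746), and their limma adjusted p was 0.382 to 0.706. The 7 lower genes included Tlr7, Helz2, Cd74, Cxcl10 and Gbp4. Gm10722 and Gm45736, also among the higher genes, were at 0 in all libraries except I/R library 1. In the simulated data, which hold independent genes and no outlying library, 23 of 157 DESeq2 calls were false, against 6 of 124 for limma.

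Sterol synthesis genes were looked at because Mvd was among the lowest named genes. Of 22 added members 5 had a positive fold change, the median was -0.22, and the limma camera p was 0.00013 at the preset correlation and 0.0982 with an estimated one, so whether they lie lower together cannot be told apart from the spread between these libraries. The added resident Kupffer cell list had 5 of 18 positive members, a median of -0.24 and a camera p of 0.00269, or 0.378 with an estimated correlation.

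For the number of genes past the threshold, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4 genes and the highest of the other 9 called 0, so 1 split reached the real count. At an unadjusted p under 0.05 the real split had 596 genes, while the split of sham library 1 and I/R libraries 1 and 2 from the rest had 1007.

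Gpnmb rose after I/R, and Ccr2 and Chil3 had higher values without passing in limma (adjusted p = 0.115 and 0.706), while the fixed macrophage and Kupffer cell list had no call (median -0.14, camera adjusted p = 0.833, and without I/R library 1 0.016 and 0.0259). In every library at least 10 of the 16 members of that list were among the top 220 genes. That count restates their abundance, so it does not test their source. How RNA of these macrophage markers came into libraries labelled as lymphatic endothelial cells stays open, since the gating markers are not given. Recruited monocytes are a candidate source, and their 20 added genes had a camera p of 0.0426 at the preset correlation, under the 0.05 named in advance, but 0.0914 with an estimated one. Cells with a lipid-associated macrophage programme are another, with 16 of 16 genes positive, a median of 0.30, and a camera p of 1.81e-05 or, with an estimated correlation, 0.0909. A rise of leukocytes of every kind would raise Ptprc, Adgre1, C1qa, C1qb and C1qc. Their median log2 fold change was -0.14 (SE 0.02 over the genes), though such abundant transcripts would hide a small added share. That SE is over genes of the same libraries and leaves out the spread between libraries. For Ptprc alone the limma SE was 0.18. For Gpnmb, Ccr2 and Chil3 the explanations and a change within the sorted cells cannot be told apart. The correlation between genes decides the 2 list tests in 3 against 3 libraries. The high baseline of the 5 transcripts leaves a small rise of all leukocytes open. The T cell gene Cd3e had 0 counts in all 6 libraries, so that gene showed no T cells in either group. Of the lymphocyte list, Il7r was higher in the I/R libraries, and only 6 of 18 members were tested.

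Il7 and lymphatic genes had higher values after I/R, which might reflect a larger share of lymphatic cells in those libraries or a change of Il7 itself. The mice carry a reporter of Il7 and the column names say "GFP plus", so cells may have been chosen on the gene compared. How such a gate would bear on the Il7 values was not tested. The 7 lymphatic markers compared with Il7 were Prox1, Flt4, Pdpn, Lyve1, Ccl21a, Mmrn1 and Reln. Their mean was 0.99 higher in the I/R libraries on the log2 scale (SE 0.61, exact permutation p = 0.2, n = 3 each). Il7 exceeded that shift by 0.67 (SE 0.36, exact permutation p = 0.2). The libraries also held sinusoidal Stab2 (rank 451) and hepatocyte Alb (rank 15), and whether other cells added to these markers was not tested. Since 3 against 3 libraries cannot go below 0.1, and sham library 3 had a marker mean of 9.66 against 11.19 and 11.47 in the other sham libraries, the share of lymphatic cells and regulation of Il7 cannot be told apart.

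Sham library 2 and I/R library 1 had 17012 and 17157 genes above 0, more than the deepest library, I/R library 2, with 14322. Of 1446 olfactory and vomeronasal receptor genes, most without a known use in liver cells, 31.05% had at least 1 count in sham library 2. The 95% exact binomial interval was 28.67 to 33.51, and the share in I/R library 1 was 35.41%. The highest share in the other 4 libraries was 9.75%. This is consistent with a low background of reads outside expressed genes, such as from genomic DNA, in 1 library of each group. With that split as a covariate limma called 0 genes, at an unchanged log2 fold change of 3.33 for Adam8, 3.12 for Gpnmb, 2.18 for F13a1 and 1.79 for Gda (adjusted p = 0.0753 to 0.0863), because the split takes 1 library from each group. With SE of 0.21 to 0.40 against 0.22 to 0.40 without it, the calls ended at 3 residual degrees of freedom in place of 4. As fold changes cannot move under this split, the fit says nothing for or against the background as the source of the 4 differences. No biological explanation was tested for this difference in detected genes.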
